A study of Homo sapiens with 12 samples.

How the data were processed

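Gene expression was measured with a human Illumina expression BeadChip on 12 arrays of 1 chip, 2 for each of 6 groups: THP-1 or BEAS-2B cells in medium, or with poultry dust extract for 1 or 3 h. Per the labels, cells were serum-starved overnight and the extract was given at 0.1% to THP-1 and at 0.25% to BEAS-2B. The design text also speaks of 6 h, and no sample of that time was used here. Groups were taken from the titles, treatment and cell line fields. The source name of the THP-1 samples reads A459, so the line was checked on marker genes. The labels do not say whether the 2 replicates of a group were separate cultures, so p-values measure the spread between these arrays, which may be technical.

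The deposited raw table holds, per the file headers, the signal of each of 47320 probes as intensity on a linear scale, its standard error over beads as intensity, the number of beads, and a detection p-value. It was made with GenomeStudio 2011.1 per the submitters' processing notes. The bead number in the deposited table is a count of beads read per probe. The detection p-value in the deposited table changes in steps that imply 770 negative control probes. The signals in it were neither background-subtracted nor scaled between arrays. Their median lay between 76.3 and 84.3 per array, with a median of 21 beads per probe and a median bead standard error of 5.51% to 5.89% of the signal. The authors' value table holds intensity on a linear scale with a median of 80.6 in every column. As read from the values, it was quantile-normalized over the 12 arrays, a step the submitters do not state: its sorted values lay within 0.16% of the mean of the sorted raw signals. All value columns could be mapped to samples.

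Signals were background-corrected with the detection p-values and quantile-normalized over the 12 arrays with neqc of limma 3.58.1 (offset 16), which gives log2 intensities. A probe was kept if its detection p was under 0.01 on both arrays of at least 1 group, which left 19045 probes. Gene symbols came from the probe annotation, where 30112 probes had 1 symbol, 8 several and 17200 none used here. Through the Entrez number, 30073 symbols were brought up to a gene table of assembly GRCh38.p14, used for names only. Of 2906 genes with more than 1 kept probe, the probe with the highest mean was used. This gave 11422 genes and 4067 probes without a name, 15489 in all. Probes without a name count in totals and were not identified.

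A linear model with 6 group means was fitted to all 12 arrays with limma (lmFit and eBayes; 6 residual and 4.3 prior degrees of freedom). It gave each dust group against the control of its line, 3 h against 1 h within each line, the difference between the lines in the dust effect at each time, and the difference between controls. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Shared genes between times were compared with independent lists and with 100 simulated data sets without effects in which both times shared the controls (seed 1), and shared genes between lines with Fisher's exact test, 2-sided.

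Before the data were examined, 17 gene lists and 5 lists of cell type markers, the named genes' rule, the tests and most alternatives were written down. The lists were chemokines, cytokines, NF-kB feedback, immediate-early transcription factors, MAP kinase feedback, EGF receptor ligands, interferon-stimulated genes, aryl hydrocarbon receptor targets, NRF2 targets, heat shock, unfolded protein and integrated stress response, adhesion with prostaglandin and coagulation genes, matrix metalloproteinases and inhibitors, pattern recognition with protease-activated receptors, G2/M, cholesterol synthesis and housekeeping. The markers were those of monocytes, epithelial cells, the A549 line, fibroblasts and lymphocytes. Lists with at least 5 measured genes were tested with limma's camera (preset correlation 0.01) in the 4 dust comparisons with control, adjusted over 64 tests. Direction is camera's, and medians of dim genes are given fitted and at their bound.

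Genes were named by rule. In each dust comparison with control these were the 10 largest rises and 5 largest falls among called genes whose 2 dust arrays lay beyond both control arrays, and up to 4 members with the smallest p of each list. In each other comparison they were the 5 largest in each direction. In every comparison 19 genes were followed: CXCL8, IL6, TNF, IL1B, CXCL1, CXCL2, CCL2, CCL20, ICAM1, PTGS2, NFKBIA, TNFAIP3, FOS, EGR1, ATF3, DUSP1, CYP1A1, CYP1B1 and HMOX1. A gene named in 1 comparison may be given in others, and the control comparison includes markers. List members named because they went against the rest of their list, and markers named in the dust comparisons, were chosen after their values were seen.

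The alternatives were no background correction, median scaling, each line normalized and fitted on its own, the authors' value table, no filter, detection on all 12 arrays, all kept probes, a replicate block, an intensity trend with robust eBayes, a threshold of 1 on the absolute log2 change, each array left out, and for lists an estimated correlation and fry. Cyclic loess was added after the data were seen. Other splits of the samples were not counted, because no group had 3 arrays. With 1 array left out, the lone array of its group was assumed to vary like the other groups.

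The steps were tested on simulated data with planted effects in THP-1 at 1 h, over 23417 simulated genes. Of 96 genes with a log2 change of 1, 54 were recovered (median estimate 0.92), and of 100 with a log2 change of 2, 95 (median estimate 1.86). None had the wrong direction, 8 unchanged genes were called in that comparison, and 4 comparisons without effects gave 0 calls. Tools were R 4.3.3, data.table (version 1.17.8), pandas 2.3.3 and matplotlib 3.10.9.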

Results

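RNA from 2 human cell lines was measured on 12 expression arrays. THP-1 is a monocytic leukemia line and BEAS-2B an immortalized line of bronchial epithelial cells. Serum-starved cells were given an extract of poultry house dust, 0.1% for THP-1 and 0.25% for BEAS-2B, for 1 or 3 h, or medium alone. Each of the 6 groups had 2 arrays. The dose differed between the lines, so any difference between their responses is one of line and dose together, and the labels do not give the duration of the controls. The probes well above background numbered 16043 and 15864 on the THP-1 control arrays, 15810 and 16896 after 1 h of dust, and 14977 and 15402 after 3 h. The BEAS-2B arrays had 15718 and 16650 such probes in control, 16487 and 17045 after 1 h, and 15411 and 15472 after 3 h. The median spread between replicate arrays (SD) lay between 0.0851 log2 for BEAS-2B control and 0.158 log2 for THP-1 after 3 h of dust.

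The largest source of variation was the cell line. The first principal component held 78.8% of the variance and parted the lines. The second held 13.1% and parted THP-1 after 3 h of dust, at 79.39 and 71.24, from THP-1 control, at -48.42 and -51.73. THP-1 after 1 h lay at -24.66 and -25.84 on that component. Changes are given below as folds with the log2 change ± its standard error (n = 2 arrays per group throughout). Where 1 of the groups was not well above background, the fold is a lower bound, written "at least". That bound is the mean of the bright group over the mean of the dim group, with each dim array set to the lowest signal among probes well above background, or to the probe's own signal where that was higher. A group with 1 dim array of 2 was given its fitted fold, which then is not exact. With that array at the same lowest signal, the folds below would be 4.42 for HMOX1 in THP-1 at 3 h against control and 4.70 against 1 h, 45.6 for ADORA2A, 191 and 348 for IL1B in THP-1 at 1 and 3 h, 6.24 for BUB1, and in BEAS-2B 3.87 for S1PR5 and 4.82 for IL23A. Those of CCL3, JUNB, NFE2 and KIF20A in THP-1 and FOSB, ICAM1, IL24, PTGES and PPP1R3C in BEAS-2B, and of IL1B between controls, would be lower too. Each named gene said to have risen or fallen against control had both dust arrays beyond both control arrays.

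The first comparison asked which genes had changed in THP-1 cells after 1 h of dust extract. The largest rises were mostly in genes of secreted signals that draw or activate white blood cells. CCL3, a chemokine for monocytes, rose 264-fold (8.04 ± 0.25, adjusted p = 4.92e-08, probe ILMN_1671509). Its close copies CCL3L1 and CCL3L3 rose 173-fold and 128-fold, which are not independent measures. CCL4L1, a copy of the chemokine CCL4, rose at least 173-fold (8.15 ± 0.22). IL1B, the precursor of a fever-inducing cytokine, rose 208-fold (7.70 ± 0.40, adjusted p = 2.54e-06), and CXCL8, which draws neutrophils, rose 118-fold (6.88 ± 0.31, adjusted p = 9.24e-07). TNF rose 75.8-fold (6.24 ± 0.50, adjusted p = 7.35e-05). The neutrophil chemokines CXCL1 and CXCL2 rose at least 46.5-fold and at least 36.6-fold, and EGR3, a transcription factor of the early response, at least 28.9-fold (5.93 ± 0.56, adjusted p = 0.000226). CCL20, which draws dendritic cells and lymphocytes, rose at least 39.8-fold (6.16 ± 0.91, adjusted p = 0.00568), and CCL2, another monocyte chemokine, 19.8-fold (4.31 ± 0.73, adjusted p = 0.0136). The CCL20 call ended without either control array or 1 h replicate 1 (adjusted p from 0.0557 to 0.057). The CCL2 call ended without any 1 of the 4 arrays compared (adjusted p from 0.0563 to 0.109).

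Among the other genes followed in every comparison, EGR1 rose 30.6-fold (4.93 ± 0.21), TNFAIP3 16.9-fold (4.08 ± 0.47), PTGS2 11.4-fold (3.52 ± 0.46), NFKBIA 7.80-fold (2.96 ± 0.25), ATF3 7.76-fold (2.96 ± 0.35) and DUSP1 at least 15.2-fold (4.24 ± 0.34). ICAM1, an adhesion molecule, rose at least 3.96-fold (2.55 ± 0.53, adjusted p = 0.0428). This call ended without any 1 array other than the 2 BEAS-2B arrays of 3 h. FOS changed by 1.47 ± 0.45 log2 (adjusted p = 0.189) and HMOX1 by 0.03 ± 0.36 (adjusted p = 0.993). CYP1B1 changed by -0.18 ± 0.18 (adjusted p = 0.789), and IL6 and CYP1A1 were not well above background in either group. The largest falls were in TXNIP, an inhibitor of thioredoxin, 2.99-fold (-1.58 ± 0.30, adjusted p = 0.0265), FRG1HP (-1.47 ± 0.27, adjusted p = 0.0221), the lymphocyte adaptor LAX1, at least 2.41-fold (-1.43 ± 0.23, adjusted p = 0.00867), FAM170B, at least 2.01-fold (-1.32 ± 0.15, adjusted p = 0.00091), and the zinc finger gene ZNF536 (-1.23 ± 0.18, adjusted p = 0.00514). Their order is by fitted change; of FRG1HP and ZNF536, 1 of the 2 dust arrays was not well above background. Of these 5 calls, that of FAM170B held without any 1 array. The others ended without a single array: TXNIP without a control array of either line or a THP-1 array of 1 h (adjusted p up to 0.192), FRG1HP and ZNF536 without control replicate 2 or 1 h replicate 1 (up to 0.162 and 0.0568), and LAX1 without 1 h replicate 2 (0.0852).

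At 1 h in THP-1, 195 genes or unnamed probes were higher and 60 lower of 15489 tested. At least 2-fold, 161 were higher and 23 lower. Under median scaling the split was 171 higher and 90 lower, and with each line normalized and fitted on its own it was 150 and 13. The count of 255 fell to 163 and 151 without THP-1 control replicate 1 or 2, and to 153 and 149 without 1 h replicate 1 or 2.

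**Figure D1:**
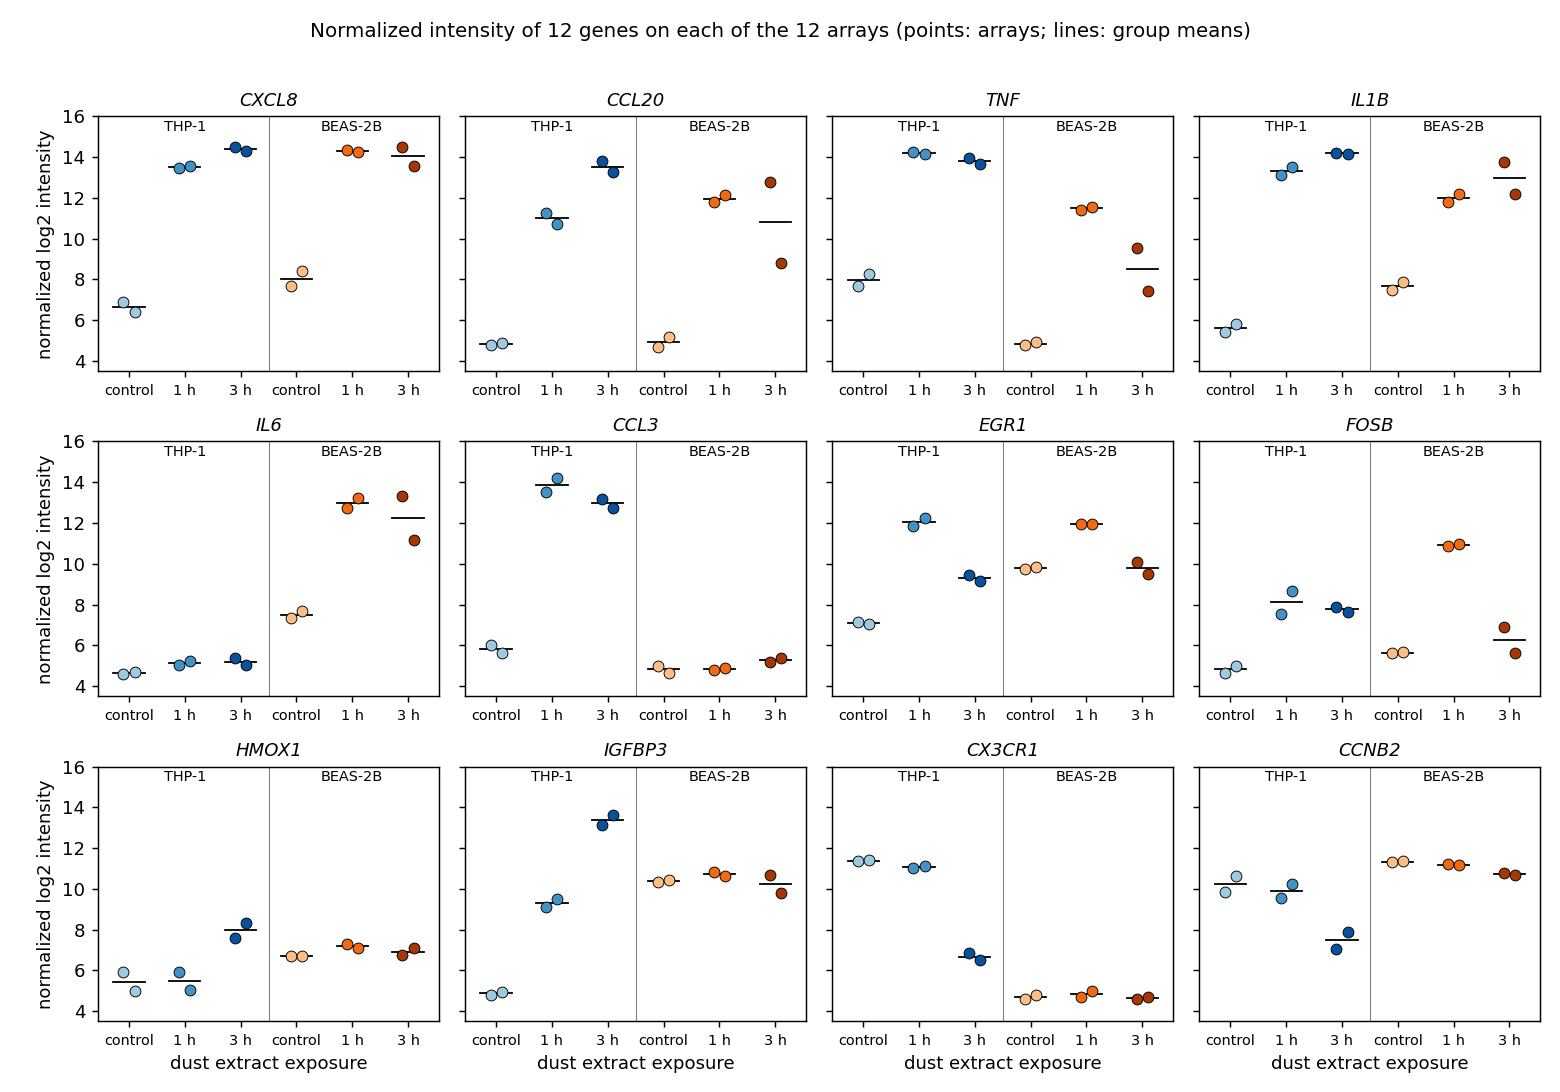
Normalized log2 intensity (vertical axes) of 12 genes on the 12 arrays, with points for arrays and lines for the means of the 2 arrays of each group. CXCL8 rose in both lines at both times, CCL3 and IGFBP3 rose in THP-1, IL6 rose in BEAS-2B, and the 2 BEAS-2B arrays of 3 h lay apart for CCL20, at 12.80 and 8.81.

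Of the 16 gene lists tested, 8 shifted upward in THP-1 at 1 h against all other genes. Of 13 measured chemokines, 7 rose (8 adjusted over the list alone), with a median of 3.64 log2, or 3.44 with dim genes at their bound (adjusted p = 3.37e-16; adjusted p = 0.0319 with an estimated correlation). Of 16 cytokines, 5 rose: EBI3, IL1A, IL1B, IL23A and TNF (also 5 adjusted over the list alone). Their list had a median of 0.22 log2, or 0 with dim genes at their bound (adjusted p = 1.87e-07; adjusted p = 0.0814 with an estimated correlation). Of 19 genes that feed back on NF-kB, the transcription factor of inflammatory signalling, 9 rose (12 adjusted over the list alone), with a median of 1.74 log2 (adjusted p = 3.72e-24; adjusted p = 0.0319 with an estimated correlation). Examples were NFKBIZ, 45.5-fold (5.51 ± 0.26), the dendritic cell marker CD83, 19.4-fold, and the mitochondrial dismutase SOD2, 6.10-fold (2.61 ± 0.15). Of 23 immediate-early transcription factors, 11 rose (16 rose and 1 fell adjusted over the list alone), with a median of 1.47 log2, or 1.20 with dim genes at their bound (adjusted p = 4.55e-21; adjusted p = 0.0648 with an estimated correlation). Examples were JUN, 5.65-fold (2.50 ± 0.18), and ZFP36, which destabilizes cytokine messages, 6.45-fold.

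Of 15 genes that feed back on MAP kinase signalling, 6 rose and 1 fell in THP-1 at 1 h (8 and 1 adjusted over the list alone), with a median of 0.62 log2, or 0.42 with dim genes at their bound (adjusted p = 1.1e-13; adjusted p = 0.00583 with an estimated correlation). IER3 rose at least 23.1-fold (5.35 ± 0.28) and the phosphatase gene DUSP2 rose 8.24-fold, while DUSP6, a phosphatase for the kinase ERK, fell 2.28-fold (-1.19 ± 0.25, adjusted p = 0.0444). Of 11 genes of the unfolded protein and integrated stress response, PPP1R15A, a phosphatase subunit that restores translation, rose 6.86-fold (2.78 ± 0.15), as the only 1 over all genes tested. Adjusted over the list alone 4 rose, and the list's median was 0.32 log2 (adjusted p = 0.000133; adjusted p = 0.0684 with an estimated correlation). Of 10 adhesion, prostaglandin and coagulation genes, ICAM1, PTGS2 and F3, the tissue factor that starts clotting, rose (4 adjusted over the list alone). F3 rose 4.76-fold (2.25 ± 0.33, adjusted p = 0.00512), a call that ended without control replicate 2 or 1 h replicate 2 (adjusted p = 0.0643 and 0.0608). The median was 0.40 log2, or 0.39 with dim genes at their bound (adjusted p = 0.000213; adjusted p = 0.325 with an estimated correlation). None of the 12 heat shock genes passed in limma, either over all genes tested or adjusted over the list alone, and 2 had an unadjusted p under 0.05. Their list shifted up by a median of 0.24 log2 (adjusted p = 0.0148; adjusted p = 0.536 with an estimated correlation), and the call ended without control replicate 1 (adjusted p = 0.902) or 1 h replicate 2 (adjusted p = 0.405).

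The other 8 tested lists did not pass in THP-1 at 1 h, with adjusted p values of 0.365 for interferon-stimulated genes (0 of 19 changed, 1 at an unadjusted p under 0.05), 0.997 for NRF2 targets (0 of 12, and 0 unadjusted), 0.141 for G2/M genes (0 of 15, 1 unadjusted), 0.0541 for cholesterol synthesis (0 of 11, 0 unadjusted), 0.501 for matrix metalloproteinases and inhibitors (0 of 7, 1 unadjusted) and 0.531 for housekeeping genes (0 of 11, 0 unadjusted), all from limma. Adjusted over the list alone, 1 metalloproteinase list member rose, and no member of the other 5 lists changed. Of 7 aryl hydrocarbon receptor targets, NFE2L2, the gene of NRF2, rose 2.12-fold (1.09 ± 0.16, adjusted p = 0.00514; 1 gene adjusted over the list alone; list adjusted p = 0.417), a call that ended without control replicate 2 or 1 h replicate 1 (adjusted p = 0.0523 and 0.0544). Of 13 pattern recognition and protease-activated receptor genes, CD14 and IRAK2 rose (3 rose and 1 fell adjusted over the list alone; list adjusted p = 0.365). Both calls were fragile: CD14 ended without any 1 of the 8 control and 1 h arrays (adjusted p up to 0.205) and under median scaling (adjusted p = 0.0783), and IRAK2 without any 1 array other than the 2 BEAS-2B arrays of 3 h (adjusted p up to 0.255). Median and mean, or median and test, differed in sign for the aryl hydrocarbon receptor, NRF2 and receptor lists. Only 4 of 7 ligands of the EGF receptor were measured, too few to test, and none rose (1 adjusted over the list alone and 1 at an unadjusted p under 0.05). Of the cell type markers, CD14 was the only 1 that changed.

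In THP-1 cells after 3 h of dust extract, chemokine and cytokine genes were again among the largest rises, and a far larger part of the measured genes had changed than at 1 h. CCL4L1 rose at least 319-fold (9.03 ± 0.22, adjusted p = 5.52e-09), IL1B 379-fold (8.57 ± 0.40, adjusted p = 1.64e-07), CXCL8 217-fold (7.76 ± 0.31, adjusted p = 6.21e-08) and CCL20 at least 232-fold (8.70 ± 0.91, adjusted p = 3.14e-05). IL23A, a subunit of interleukin 23, rose 188-fold (7.55 ± 0.18, adjusted p = 5.52e-09, probe ILMN_1715603). The other largest rises included IGFBP3, a binding protein for insulin-like growth factors, at least 209-fold (8.52 ± 0.27, adjusted p = 1.6e-08), TNFAIP6, a hyaluronan-binding protein, at least 167-fold (8.12 ± 0.52), and CCN2, also known as connective tissue growth factor, at least 188-fold (7.96 ± 0.22, adjusted p = 7.93e-09). IL7R, the receptor of interleukin 7, rose at least 79.2-fold (7.20 ± 0.41) and CXCL2 at least 69.2-fold (7.29 ± 0.54).

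The largest falls in THP-1 at 3 h included those of 2 chemokine receptors. CX3CR1, the fractalkine receptor, fell 25.8-fold (-4.69 ± 0.16, adjusted p = 3.1e-08, probe ILMN_2088437), and CCR2, the receptor of CCL2, fell 20.9-fold (-4.38 ± 0.15, adjusted p = 3.3e-08). NFE2, a transcription factor of blood cells, fell 21.1-fold (-4.40 ± 0.29), RGS18, a regulator of G protein signalling, 15.9-fold (-3.99 ± 0.17) and KLHL24, a ubiquitin ligase adaptor, at least 6.93-fold (-4.01 ± 0.17). Among the genes followed in every comparison, TNF was 57.8-fold higher (5.85 ± 0.50), PTGS2 24.9-fold, TNFAIP3 17.6-fold, CCL2 10.2-fold (3.35 ± 0.73, adjusted p = 0.00345), NFKBIA 7.76-fold, EGR1 4.53-fold, FOS 4.30-fold (2.10 ± 0.45, adjusted p = 0.00322) and ATF3 3.74-fold. CXCL1 rose at least 94.5-fold, ICAM1 at least 18.1-fold and DUSP1 at least 15.9-fold. HMOX1, heme oxygenase 1, rose 5.67-fold (2.50 ± 0.36, adjusted p = 0.000255) and CYP1B1, a target of the aryl hydrocarbon receptor, 1.58-fold (0.66 ± 0.18, adjusted p = 0.0115), a call that ended without 3 h replicate 1 (adjusted p = 0.0602) and under median scaling (adjusted p = 0.283). IL6 and CYP1A1 were not well above background in either group.

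At 3 h in THP-1, 2966 genes or probes were higher and 4101 lower, 45.6% of those tested. At least 2-fold, 1429 were higher and 1880 lower, and 122 were at least 16-fold higher. The arrays of this group had the lowest 75th percentiles of signal, 126 and 127 against 144 to 181 on the other 10 arrays. Median scaling moved the median log2 change of all genes from -0.05 to -0.30 and the split to 1650 higher and 6046 lower. No gene named here and no list called here changed direction under median scaling.

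Of the tested lists, 9 shifted upward and 2 downward in THP-1 at 3 h. All 19 measured NF-kB feedback genes rose (19 adjusted over the list alone), with a median of 4.14 log2 (adjusted p = 6.88e-17; adjusted p = 0.0539 with an estimated correlation). Examples were SOD2, 44.6-fold (5.48 ± 0.15), the subunit gene NFKB2, 25.9-fold (4.70 ± 0.20), and the adaptor TRAF1, at least 29.9-fold. Of 13 chemokines 11 rose (11 adjusted over the list alone), with a median of 4.75 log2, or 4.22 with dim genes at their bound (adjusted p = 1.17e-07; adjusted p = 0.103 with an estimated correlation). Of 16 cytokines 9 rose (9 adjusted over the list alone), with a median of 1.86 log2, or 1.36 with dim genes at their bound (adjusted p = 1.4e-06; adjusted p = 0.0987 with an estimated correlation). EBI3, a subunit of interleukins 27 and 35, rose 114-fold (6.83 ± 0.31) and IL12B at least 4.53-fold. Of 12 NRF2 targets, genes of antioxidant defence, 9 rose (10 adjusted over the list alone), with a median of 1.43 log2 (adjusted p = 6.83e-06; adjusted p = 0.0319 with an estimated correlation). SRXN1, which repairs oxidized peroxiredoxins, rose 20.1-fold (4.33 ± 0.16, adjusted p = 4.61e-08), GCLM, of glutathione synthesis, 10.8-fold (3.44 ± 0.23), TXNRD1, thioredoxin reductase, 5.65-fold (2.50 ± 0.16) and NQO1, a quinone reductase, 2.76-fold (1.47 ± 0.17).

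Of 23 immediate-early factors, 17 rose and 2 fell in THP-1 at 3 h (17 and 2 adjusted over the list alone), with a median of 1.90 log2, or 1.72 with dim genes at their bound (adjusted p = 1.08e-05; adjusted p = 0.325 with an estimated correlation). NR4A2 rose 10.3-fold and JUNB 6.36-fold, while KLF2 fell 1.78-fold (-0.83 ± 0.18) and KLF4, a factor of monocyte differentiation, fell 3.66-fold (-1.87 ± 0.25). Of 15 MAP kinase feedback genes, 9 rose and SPRY2 fell (9 and 1 adjusted over the list alone), with a median of 1.60 log2, or 0.70 with dim genes at their bound (adjusted p = 2.82e-05; adjusted p = 0.0272 with an estimated correlation). IER3 rose at least 53.8-fold and SPRED2 9.40-fold. Of 10 adhesion, prostaglandin and coagulation genes 7 rose (7 adjusted over the list alone), with a median of 2.33 log2 (adjusted p = 2.31e-05; adjusted p = 0.254 with an estimated correlation); examples were THBS1, thrombospondin 1, at least 8.77-fold, and the urokinase gene PLAU, 5.10-fold. Of 11 stress response genes 8 rose (8 adjusted over the list alone), with a median of 0.74 log2 (adjusted p = 0.00271; adjusted p = 0.11 with an estimated correlation), among them DDIT4, 2.94-fold, and the chaperone HSPA5, 2.13-fold. Of 19 interferon-stimulated genes 8 rose and RSAD2 fell (9 and 1 adjusted over the list alone), with a median of 0.52 log2, or 0.40 with dim genes at their bound (adjusted p = 0.01; adjusted p = 0.348 with an estimated correlation). GBP2 rose 10.4-fold (3.38 ± 0.35) and ISG20 5.96-fold (2.58 ± 0.18), and the list's call ended with all kept probes tested (adjusted p = 0.0661).

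The G2/M list fell in THP-1 at 3 h: 13 of 15 measured genes of cell division were lower (15 adjusted over the list alone), with a median of -1.87 log2 (adjusted p = 1.53e-05; adjusted p = 0.348 with an estimated correlation). KIF20A fell 9.73-fold (-3.28 ± 0.29), BUB1 7.33-fold (-2.87 ± 0.42), CCNB2 6.72-fold (-2.75 ± 0.31) and CDC20 5.26-fold (-2.40 ± 0.34). Of 13 receptor and adaptor genes of pattern recognition 9 fell and IRAK2 rose 41.5-fold (9 and 1 adjusted over the list alone). MYD88, the adaptor of most Toll-like receptors, fell 2.41-fold (-1.27 ± 0.18), and TLR6 and TLR1 fell at least 1.39-fold and at least 1.18-fold. That list's median was -1.25 log2, or -0.37 with dim genes at their bound (adjusted p = 0.031; adjusted p = 0.11 with an estimated correlation). Its call ended without 3 h replicate 2 (adjusted p = 0.0745) and under median scaling (adjusted p = 0.0919), and with only probes well above background on all 12 arrays its median turned to 0.03 (adjusted p = 0.87).

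The remaining lists did not pass in THP-1 at 3 h. Of 7 aryl hydrocarbon receptor targets, CYP1B1, NFE2L2 and NQO1 rose (3 adjusted over the list alone; list adjusted p = 0.125), and NQO1 is also an NRF2 target. Of 12 heat shock genes 4 rose and 1 fell (3 and 1 adjusted over the list alone; list adjusted p = 0.252); HSPA1A rose 1.75-fold (0.80 ± 0.17, adjusted p = 0.00258). Of 7 matrix metalloproteinases and inhibitors, MMP1 rose at least 3.09-fold, TIMP3 rose 2.35-fold, MMP9 and TIMP1 also rose, and TIMP2 fell (4 and 1 adjusted over the list alone; list adjusted p = 0.0713). The MMP9 call ended without control replicate 1 or 3 h replicate 2 (adjusted p = 0.0521 and 0.0514), and another probe of TIMP2 was called in the opposite direction. Of 11 cholesterol synthesis genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; list adjusted p = 0.634, with a median and a mean of opposite sign). Of 11 housekeeping genes 2 rose, TFRC 1.86-fold and HPRT1 1.32-fold (1 adjusted over the list alone; list adjusted p = 0.531). The HPRT1 call ended without any 1 array other than the 2 THP-1 arrays of 1 h (adjusted p up to 0.181). Of 4 EGF receptor ligands NRG1 rose (adjusted p = 0.037), a call that ended without any 1 control array, BEAS-2B array of 1 h, THP-1 1 h replicate 2 or THP-1 3 h replicate 1 (adjusted p up to 0.278), and none rose adjusted over the list alone.

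Of 17 monocyte markers 7 fell and 1 rose in THP-1 at 3 h. CSF1R, the receptor of the monocyte growth factor, fell 2.13-fold (-1.09 ± 0.18), CORO1A fell 3.08-fold (-1.62 ± 0.20), and SPI1, the master factor of myeloid cells, rose 2.26-fold (1.18 ± 0.15). Of 15 epithelial markers LAMB3 and MET rose and CAV1 fell. Of 9 genes high in the A549 lung line, AKR1C2, AKR1C3, ALDH1A1 and NQO1 rose. None of the 3 fibroblast markers was called (limma, 0 also at an unadjusted p under 0.05). All 3 were at background in THP-1 in control and at 3 h, so no fall could be seen. Of 3 lymphocyte markers CD79B fell.

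In BEAS-2B cells, 1 h of dust extract raised chemokine, cytokine and immediate-early genes, and almost every gene called was higher. CXCL2 rose at least 107-fold (7.06 ± 0.54, adjusted p = 0.000155), CXCL8 77.7-fold (6.28 ± 0.31, adjusted p = 1.15e-05, probe ILMN_2184373), TNF at least 57.4-fold (6.64 ± 0.50) and CCL20 at least 80.2-fold (7.04 ± 0.91, adjusted p = 0.00304; 0.0513 without 1 h replicate 2). IL6, a cytokine of the acute phase, rose 44.6-fold (5.48 ± 0.52, adjusted p = 0.000456). TNFAIP3, the NF-kB inhibitor A20, rose 40.6-fold (5.34 ± 0.47), FOSB 38.4-fold (5.26 ± 0.41), CXCL1 32.6-fold (5.03 ± 0.39), NFKBIZ 31.2-fold (4.96 ± 0.26) and IL1A 25.3-fold (4.66 ± 0.57, adjusted p = 0.00242). IL1B rose 19.8-fold (4.31 ± 0.40), PTGS2 at least 11.4-fold, ATF3 9.63-fold, NFKBIA 8.30-fold, DUSP1 7.11-fold and EGR1 4.41-fold. CCL2 rose 16.4-fold (4.03 ± 0.73, adjusted p = 0.026), ICAM1 7.22-fold (2.85 ± 0.53, adjusted p = 0.0293) and FOS at least 4.73-fold (2.66 ± 0.45, adjusted p = 0.0177). Each of these 3 calls ended without any of the 4 arrays compared, and those of CCL2 and ICAM1 also without either THP-1 control array. HMOX1 changed by 0.49 ± 0.36 log2, CYP1A1 by 0.18 ± 0.21 and CYP1B1 by 0.16 ± 0.18 (adjusted p = 0.998 for each).

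Few genes fell in BEAS-2B at 1 h. PPP1R3C, a regulator of glycogen synthesis, fell 2.36-fold (-1.24 ± 0.15, adjusted p = 0.00242). The others with the largest falls were SNAI2, a repressor of epithelial genes (-1.16, adjusted p = 0.0263), ZNF792 (at least 1.14-fold), ZSCAN2 (-0.97, adjusted p = 0.041) and CTSK, a cathepsin (-0.89, adjusted p = 0.00709). All but the PPP1R3C call ended without single arrays: SNAI2 without either control of either line or 1 h replicate 1 (adjusted p up to 0.248), ZNF792 without any of the 4 arrays compared (up to 0.146), ZSCAN2 without these or the THP-1 control and 1 h arrays (up to 0.409), and CTSK without either BEAS-2B control or 1 h replicate 1 (up to 0.113). In all, 171 genes or probes were higher and 12 lower, 148 and 4 of them at least 2-fold. The count of 183 fell to 72 and 81 without BEAS-2B control replicate 1 or 2 and to 89 and 75 without 1 h replicate 1 or 2. It rose to 279 and 280 without BEAS-2B 3 h replicate 1 or 2. Those arrays enter this comparison only through the shared estimate of spread and the joint normalization.

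In BEAS-2B at 1 h, 9 lists shifted upward. Of 23 immediate-early factors 16 rose (18 adjusted over the list alone), with a median of 1.76 log2 (adjusted p = 1.63e-49; adjusted p = 0.0272 with an estimated correlation), among them ZFP36, 7.40-fold, and BHLHE40, 5.75-fold. Of 13 chemokines 6 rose (10 adjusted over the list alone), with a median of 1.83 log2, or 1.49 with dim genes at their bound (adjusted p = 3.72e-24; adjusted p = 0.0272 with an estimated correlation); CXCL5 rose at least 2.75-fold. Of 16 cytokines 6 rose (8 adjusted over the list alone), with a median of 0.77 log2, or 0.45 with dim genes at their bound (adjusted p = 5.44e-18; adjusted p = 0.0272 with an estimated correlation); IL24 rose 4.86-fold (2.28 ± 0.16). Of 19 NF-kB feedback genes 8 rose (15 adjusted over the list alone), with a median of 1.12 log2 (adjusted p = 1.25e-32; adjusted p = 0.0272 with an estimated correlation); NFKBIE rose 4.21-fold. Of 15 MAP kinase feedback genes 7 rose (11 adjusted over the list alone), with a median of 1.10 log2 (adjusted p = 6.26e-27; adjusted p = 0.00144 with an estimated correlation); the phosphatase gene DUSP5 rose 7.28-fold and SPRY4 5.36-fold. Of 10 adhesion, prostaglandin and coagulation genes 6 rose (9 adjusted over the list alone), with a median of 1.72 log2 (adjusted p = 4.23e-22; adjusted p = 0.0319 with an estimated correlation). PLAU rose 3.40-fold (0.0512 without control replicate 1) and PLAUR, the urokinase receptor, 3.66-fold (up to 0.166 without either control or 1 h replicate 2).

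Of 11 stress response genes, PPP1R15A, 4.58-fold (2.19 ± 0.15), and DDIT3 rose in BEAS-2B at 1 h (2 adjusted over the list alone), with a median of 0.20 log2 (adjusted p = 8.48e-07; adjusted p = 0.0319 with an estimated correlation). The DDIT3 call (adjusted p = 0.0372) ended without either control array of either line, either THP-1 array of 3 h or BEAS-2B 1 h replicate 2 (up to 0.416). Of 7 aryl hydrocarbon receptor targets TIPARP rose (2 adjusted over the list alone), with a median of 0.16 log2 (adjusted p = 0.0214; adjusted p = 0.149 with an estimated correlation). TIPARP rose 1.79-fold (0.84 ± 0.16, adjusted p = 0.0372), a call that ended without any 1 control array of either line or BEAS-2B array of 1 h (up to 0.395). None of the 13 pattern recognition genes passed in limma (2 adjusted over the list alone, 3 at an unadjusted p under 0.05), with a median of 0.03 log2, or 0 with dim genes at their bound (list adjusted p = 0.026; adjusted p = 0.103 with an estimated correlation). Both list calls ended without control replicate 2 (adjusted p = 0.104 and 0.09), and that of pattern recognition also without 1 h replicate 1 (adjusted p = 0.102). Of the 4 measured EGF receptor ligands HBEGF, 10.8-fold, and TGFA, 1.76-fold, rose (3 adjusted over the list alone). The HBEGF call ended without control replicate 1 or either 1 h array (up to 0.0643) and the TGFA call without any of the 4 arrays compared (up to 0.312). The other 7 lists did not shift. Of 19 interferon-stimulated genes IRF1, a factor of interferon responses, rose 5.49-fold (1 adjusted over the list alone; list adjusted p = 0.382), a call that ended without any of the 4 arrays compared (up to 0.0774). No member was called in limma among 12 NRF2 targets (list adjusted p = 0.389; 1 at an unadjusted p under 0.05), 12 heat shock genes (0.869; 0 unadjusted), 7 metalloproteinases and inhibitors (0.504; 1 unadjusted, 1 adjusted over the list alone), 15 G2/M genes (0.619; 0 unadjusted), 11 cholesterol synthesis genes (0.125; 0 unadjusted) and 11 housekeeping genes (0.844; 0 unadjusted). Median and mean differed in sign for the interferon and metalloproteinase lists. Of the cell type markers LAMB3, a chain of laminin, was the only 1 that changed, 2.76-fold higher (adjusted p = 0.0497).

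In BEAS-2B cells after 3 h of dust extract, chemokine and interleukin genes stayed high while few immediate-early genes passed against control. CXCL8 rose 64.5-fold (6.01 ± 0.31, adjusted p = 4.8e-06), IL1B 39.4-fold (5.30 ± 0.40, adjusted p = 6.74e-05), CXCL1 27.4-fold (4.77 ± 0.39), IL6 27.0-fold (4.75 ± 0.52, adjusted p = 0.000674) and IL1A 25.9-fold (4.69 ± 0.57). CXCL5 and CXCL6, chemokines for neutrophils, rose at least 16.2-fold (4.79 ± 0.24, adjusted p = 3.75e-06) and at least 19.6-fold (4.63 ± 0.43). MMP3, a protease that degrades matrix proteins, rose 23.9-fold (4.58 ± 0.48, adjusted p = 0.000549) and IL24 22.1-fold (4.47 ± 0.16, adjusted p = 9.21e-07, probe ILMN_1774685). CCL20 rose at least 35.7-fold (5.87 ± 0.91, adjusted p = 0.00495; 0.0567 without control replicate 1). CXCL2 rose at least 16.3-fold, TNFAIP3 11.6-fold, PTGS2 at least 9.03-fold, TNF at least 7.22-fold (3.65 ± 0.50) and NFKBIA 3.95-fold. CCL2 rose 13.6-fold (3.76 ± 0.73, adjusted p = 0.0145) and ICAM1 7.03-fold (2.81 ± 0.53, adjusted p = 0.0127). Both calls ended without either control array.

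Of the other genes followed in every comparison, EGR1 in BEAS-2B at 3 h changed by -0.01 ± 0.21 log2 (adjusted p = 0.993), ATF3 by 0.69 ± 0.35 (0.302), DUSP1 by 0.43 ± 0.34 (0.518), HMOX1 by 0.22 ± 0.36 (0.795) and CYP1B1 by 0.04 ± 0.18 (0.938), and FOS was not well above background in either group. CYP1A1, a detoxifying enzyme under the aryl hydrocarbon receptor, fell 2.02-fold (-1.01 ± 0.21, adjusted p = 0.0184), a call that ended without either control array or 3 h replicate 2 (0.0755 to 0.172). The largest falls were in TNNI2, a troponin, at least 3.17-fold (-2.43 ± 0.27), ACKR3, a scavenging chemokine receptor, at least 2.09-fold, S1PR5, a receptor of sphingosine 1-phosphate, 5.25-fold (-2.39 ± 0.30, adjusted p = 0.00152), RAB7B, at least 2.96-fold, and FAT2, a cadherin, at least 2.82-fold (-2.21 ± 0.16). In all, 505 genes or probes were higher and 342 lower, 280 and 86 of them at least 2-fold. Under median scaling the split was 475 and 618, and with each line normalized and fitted on its own it was 621 and 643. The 2 arrays of this group differed in the size of the response: in replicates 1 and 2, CCL20 had a log2 intensity of 12.80 and 8.81, CCL2 of 13.80 and 10.84, CXCL2 of 10.76 and 8.59, IL6 of 13.34 and 11.17 and TNF of 9.54 and 7.45. The count of 847 was 521 without 3 h replicate 1, 217 without control replicate 1 and 271 without control replicate 2.

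In BEAS-2B at 3 h, 8 lists shifted upward and 1 downward. Of 13 chemokines 10 rose (10 adjusted over the list alone), with a median of 3.76 log2 (adjusted p = 5.97e-18; adjusted p = 0.0319 with an estimated correlation); CCL5 rose 4.01-fold. Of 16 cytokines 9 rose (10 adjusted over the list alone), with a median of 1.97 log2, or 1.51 with dim genes at their bound (adjusted p = 2.41e-12; adjusted p = 0.0328 with an estimated correlation); IL23A rose 5.87-fold. Of 19 NF-kB feedback genes 14 rose (17 adjusted over the list alone), with a median of 1.85 log2 (adjusted p = 1.28e-22; adjusted p = 0.0319 with an estimated correlation); SOD2 rose 7.73-fold (2.95 ± 0.15), TNIP1 4.22-fold and NFKB2 4.07-fold. Of 15 MAP kinase feedback genes 9 rose (9 adjusted over the list alone), with a median of 0.66 log2 (adjusted p = 1.35e-10; adjusted p = 0.00848 with an estimated correlation); SPRY4 rose 4.82-fold and PHLDA1, a target of ERK signalling, 4.16-fold. Of 10 adhesion, prostaglandin and coagulation genes 7 rose (9 adjusted over the list alone), with a median of 1.69 log2 (adjusted p = 3.24e-11; adjusted p = 0.0944 with an estimated correlation). PLAUR rose 4.92-fold and PTGES, a prostaglandin E synthase, 2.70-fold (1.44 ± 0.12).

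Of 23 immediate-early factors 3 rose in BEAS-2B at 3 h: FOSL1, 4.29-fold (2.10 ± 0.30), JUN, 1.85-fold, and KLF4, 2.44-fold (7 adjusted over the list alone). The list's median was 0.47 log2 (adjusted p = 1.24e-05; adjusted p = 0.325 with an estimated correlation). The JUN and KLF4 calls ended without either control array or 3 h replicate 1 (up to 0.147 and 0.109). Of 11 stress response genes HSPA5, PPP1R15A and SDF2L1 rose (8 adjusted over the list alone), with a median of 0.70 log2 (adjusted p = 8.94e-07; adjusted p = 0.0319 with an estimated correlation). These 3 calls ended without a control array or, for SDF2L1, 3 h replicate 2: HSPA5 without replicate 2 of the controls (0.0697), and the other 2 without either control (up to 0.0579 and 0.14). Of 13 pattern recognition genes IRAK2, 10.7-fold (3.42 ± 0.34), and the inflammasome gene NLRP3, at least 2.62-fold, rose (3 adjusted over the list alone), with a median of 0.11 log2, or 0.06 with dim genes at their bound (adjusted p = 0.0109; adjusted p = 0.0801 with an estimated correlation). The G2/M list shifted down by a median of -0.44 log2 (adjusted p = 0.0098; adjusted p = 0.582 with an estimated correlation), while 0 of its 15 genes were called in limma (0 adjusted over the list alone, 3 at an unadjusted p under 0.05), and its call ended without 3 h replicate 1 (adjusted p = 0.0857). Of 4 EGF receptor ligands TGFA, 4.76-fold (2.25 ± 0.15), and HBEGF, 7.59-fold, rose (3 adjusted over the list alone; HBEGF 0.0624 without control replicate 1).

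The other 7 lists did not pass in BEAS-2B at 3 h. Of 19 interferon-stimulated genes ISG20 rose 3.06-fold and IFIT1 fell 1.92-fold (2 and 1 adjusted over the list alone; list adjusted p = 0.912), and the IFIT1 call ended without either control array or 3 h replicate 2 (up to 0.172). Of 7 aryl hydrocarbon receptor targets TIPARP rose 1.76-fold and CYP1A1 fell (1 and 3 adjusted over the list alone; list adjusted p = 0.43), and the TIPARP call ended without either control array or 3 h replicate 1 (up to 0.161). Of 7 metalloproteinases and inhibitors MMP3 and MMP1 rose (3 rose and 2 fell adjusted over the list alone; list adjusted p = 0.0671). MMP1 rose at least 1.57-fold (adjusted p = 0.0236), a call that ended without either control array or 3 h replicate 2 (up to 0.166). No member was called in limma among 12 NRF2 targets (list adjusted p = 0.747; 2 at an unadjusted p under 0.05), 12 heat shock genes (0.501; 1 unadjusted), 11 cholesterol synthesis genes (0.749; 1 unadjusted) and 11 housekeeping genes (0.634; 1 unadjusted), nor adjusted over these lists alone. Median and mean differed in sign for the interferon and NRF2 lists. Among the cell type markers, LAMB3, 3.64-fold, EGFR, 1.45-fold, and CORO1A, 2.45-fold, rose, and ITGB4, 1.48-fold, and the fibroblast marker PDGFRB, 2.56-fold, fell.

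The arrays of 3 h and 1 h were also compared directly, within each line. In THP-1, IL7R rose at least 82.9-fold from 1 to 3 h (7.20 ± 0.41, adjusted p = 9.57e-07), LAMP3, a lysosomal protein of mature dendritic cells, at least 67.0-fold, STAT4, a transcription factor downstream of interleukin 12, 78.9-fold (6.30 ± 0.19, adjusted p = 2.92e-08), ADORA2A, an adenosine receptor, 64.0-fold (6.00 ± 0.45) and G0S2 at least 39.2-fold. CX3CR1 fell 21.1-fold (-4.40 ± 0.16, adjusted p = 7.63e-08), WIPF1 at least 7.66-fold, and RGS18, CCR2 and NFE2 by 13.2-fold, 13.2-fold and 10.7-fold. HMOX1 rose 5.56-fold, CYP1B1 1.80-fold and ICAM1 4.57-fold (adjusted p = 0.00759; 0.0661 without 1 h replicate 2), and EGR1 fell 6.76-fold (-2.76 ± 0.21). CCL20 rose 5.83-fold (adjusted p = 0.0479), CXCL8 1.84-fold (0.0433) and ATF3 fell 2.07-fold (0.0373). CCL20 ended without any 1 array other than the 2 BEAS-2B arrays of 3 h. CXCL8 ended without any THP-1 dust array or BEAS-2B array of 1 h. ATF3 ended without any control array, any BEAS-2B array of 1 h or replicate 2 of THP-1 at 1 h or 3 h. TNF changed by -0.39 ± 0.50 log2 (adjusted p = 0.583). CXCL1, CXCL2, CCL2, IL1B, PTGS2, NFKBIA, TNFAIP3, FOS and DUSP1 did not pass either, and IL6 and CYP1A1 stayed at background. Of 12 NRF2 targets 10 rose, and of 19 NF-kB feedback genes 16 rose. Of 23 immediate-early factors 5 rose and 9 fell. In all 2609 genes or probes were higher at 3 h and 3507 lower, or 1481 and 4863 under median scaling, which moved the median of all genes from -0.03 to -0.21 log2.

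In BEAS-2B, SGPP2, an enzyme of sphingosine 1-phosphate metabolism, rose 14.1-fold from 1 to 3 h (3.81 ± 0.35, adjusted p = 0.000521), PI3, an elastase inhibitor, 6.19-fold (2.63 ± 0.31) and SAA4, a serum amyloid gene, 6.04-fold (2.60 ± 0.14). CXCL6 rose 6.98-fold (adjusted p = 0.00835) and MMP3 6.81-fold (0.0148), and both calls ended without 1 h replicate 1 (0.0895 and 0.16), that of CXCL6 also without 1 h replicate 2 (0.0667). FOSB fell 24.9-fold (-4.64 ± 0.41, adjusted p = 0.000394) and EGR1 4.43-fold (-2.15 ± 0.21, adjusted p = 0.000594). TNF fell 7.95-fold (-2.99 ± 0.50, adjusted p = 0.0119), CXCL2 6.57-fold (0.026), ATF3 5.96-fold (0.00474), DUSP1 5.27-fold (0.00555), CYP1A1 2.28-fold (0.0148), FOS at least 4.31-fold (0.0107) and EGR3 at least 3.32-fold. Each of these 7 calls ended without at least 1 array: all 7 without 1 h replicate 1 (0.0543 to 0.159), all but DUSP1 without 1 h replicate 2 (0.0509 to 0.181), FOS and CYP1A1 without 3 h replicate 2 (0.0575 and 0.0559), EGR3 without either 3 h array (0.0688 and 0.0942), and CXCL2 without control replicate 1 (0.0501). CXCL8 changed by -0.27 ± 0.31 log2 (adjusted p = 0.748) and IL6 by -0.72 ± 0.52 (0.56). CXCL1, CCL2, CCL20, IL1B, ICAM1, PTGS2, NFKBIA, TNFAIP3, CYP1B1 and HMOX1 did not pass either. Of 23 immediate-early factors 13 fell and none rose (limma). In all 219 genes or probes were higher at 3 h and 203 lower, or 199 and 330 under median scaling. The count of 422 was 77 and 106 without 1 h replicate 1 or 2, and 252 and 259 without control replicate 1 or 2, which enter only through the spread.

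The genes raised early in THP-1 were mostly still raised later. Of the 195 genes or probes higher at 1 h, 179 were higher at 3 h as well, and 98 rose further from 1 to 3 h, 30 fell and 67 did neither. In BEAS-2B, of 171 higher at 1 h, 105 were higher at 3 h, and 15 rose further, 52 fell and 104 did neither. With those lower at both times, 232 genes in THP-1 and 110 in BEAS-2B kept their direction, and 3 and 1 turned it. Independent lists of these sizes would share 37.3 higher and 15.9 lower genes in THP-1, where 179 and 53 were shared, and 5.58 higher and 0.27 lower in BEAS-2B, where 105 and 5 were shared. Both times use the same control arrays, so part of the shared genes can stem from them. In 100 simulated data sets without effects at most 1 gene was shared in THP-1 and 0 in BEAS-2B, but data without effects give almost no calls, so the size of that part stays open. The 232 fell to 148 and 140 without THP-1 control replicate 1 or 2, and to 141 and 140 without 1 h replicate 1 or 2. The 110 became 31 and 37 without BEAS-2B control replicate 1 or 2, 58 and 51 without 1 h replicate 1 or 2, and 190 without 3 h replicate 2.

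A set of genes rose in both lines. At 1 h, 52 genes or probes were higher in both, against 2.15 for independent lists (Fisher's exact test, 2-sided, p = 8.93e-59), and 2 changed in opposite directions. No gene was lower in both at 1 h (limma, from 60 and 12 lower genes at an adjusted p, and 1841 and 976 genes of either direction at an unadjusted p under 0.05). At 3 h, 260 were higher in both (96.7 for independent lists, exact p = 6.3e-62), 163 lower in both (90.6 for independent lists, exact p = 2.37e-17) and 69 opposite. Genes are not independent samples, so these p values are descriptive. Of all genes and probes tested, 32 were higher in all 4 comparisons, 30 of them named, and none was lower in all 4. Among the 30 were CXCL8, CXCL1, CXCL2, CCL2, CCL20, IL1A, IL1B, TNF, PTGS2, SOD2, TNFAIP3, NFKBIA and NFKBIZ. The 52 shared at 1 h became 33 and 34 without BEAS-2B control replicate 1 or 2, 30 without BEAS-2B 1 h replicate 2 and 90 without either BEAS-2B array of 3 h. The 423 shared at 3 h became 104 and 123 without BEAS-2B control replicate 1 or 2 and 224 without BEAS-2B 3 h replicate 1.

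Whether the dust effect differed between the lines was tested as the effect in BEAS-2B minus that in THP-1, with fitted log2 values that are neither exact nor bounds where a group was dim. IL6, EDN1 and G0S2 were at background in THP-1, and CCL3, CCL3L3 and CCL4L1 in BEAS-2B, in control and at 1 h, and CCL4L1 in THP-1 control and G0S2 in BEAS-2B control as well. At 1 h, CCL4L1 (-8.04 ± 0.32, adjusted p = 1.28e-06), CCL3 (-8.03 ± 0.35), CCL3L1 (-7.50 ± 0.37), CCL3L3 (-6.91 ± 0.47) and KCNJ2, a potassium channel (-4.23 ± 0.48), had lower effects in BEAS-2B, as had EGR1 (-2.79 ± 0.29, adjusted p = 0.00204). DUSP6 had a higher effect in BEAS-2B (2.96 ± 0.35, adjusted p = 0.00372), having fallen in THP-1 and risen 3.41-fold in BEAS-2B. IL6 (4.96 ± 0.73, adjusted p = 0.014), the endothelin gene EDN1 (3.61 ± 0.51, 0.011), TRIB1 (3.49 ± 0.48, 0.00982) and G0S2 (2.94 ± 0.54, 0.0485) also had higher effects in BEAS-2B, and IL1B a lower 1 (-3.39 ± 0.57, 0.0271). The calls of IL6, IL1B and G0S2 ended without any 1 of the 8 control and 1 h arrays (up to 0.0955, 0.157 and 0.252), that of EDN1 without any of these but THP-1 1 h replicate 2 (up to 0.0724), and that of TRIB1 without any of the 4 BEAS-2B arrays or THP-1 control replicate 2 (up to 0.0656). CXCL8 (-0.60 ± 0.44, adjusted p = 0.971), TNF (0.39 ± 0.71), CXCL1, CXCL2, CCL2, CCL20, ICAM1, PTGS2, NFKBIA, TNFAIP3, FOS, ATF3, DUSP1, CYP1A1, CYP1B1 and HMOX1 did not pass. In all 88 genes or probes differed, 41 with a higher and 47 with a lower effect in BEAS-2B. Without 1 array, the count was 40 and 50 for THP-1 control replicates 1 and 2, 52 and 58 for THP-1 1 h, 34 and 30 for BEAS-2B control, 34 and 36 for BEAS-2B 1 h, and 143 for either BEAS-2B array of 3 h.

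At 3 h, 4114 genes or probes had a different effect, 2299 higher and 1815 lower in BEAS-2B (3447 and 1180 under median scaling, which moved the median of all genes from 0.03 to 0.25 log2). The lower effects were largest for CCL4L1 (-8.67 ± 0.32), IGFBP3 (-8.66 ± 0.38, adjusted p = 6.31e-07), CCN2 (-7.67 ± 0.32), CCL3 (-6.70 ± 0.35) and SLC16A10, an amino acid transporter (-6.35 ± 0.29). The higher fitted effects were largest for CXCL5 (5.04 ± 0.33, adjusted p = 5.93e-06), CX3CR1 (4.64 ± 0.23), CCR2 (4.51 ± 0.22), ARHGEF3 (4.45 ± 0.37) and MMP3 (4.34 ± 0.68, adjusted p = 0.00123). CX3CR1 and CCR2 were at background in BEAS-2B with and without dust, where a fall could not be seen, so their values restate the fall in THP-1. CXCL5, MMP3 and IL6 were at background in THP-1, and CCL3, CCL4L1 and FOS in BEAS-2B. So were CCL4L1, IGFBP3, CCN2, SLC16A10, DUSP1, CXCL1 and CXCL2 in THP-1 control, CXCL5, TNF and CXCL2 in BEAS-2B control and SLC16A10 in BEAS-2B at 3 h. IL6 had a higher effect in BEAS-2B (4.17 ± 0.73, adjusted p = 0.00236), and IL1B (-3.27 ± 0.57), DUSP1 (-3.87 ± 0.48), HMOX1 (-2.28 ± 0.51) and EGR1 (-2.19 ± 0.29) lower ones. CXCL8 (-1.75 ± 0.44, 0.0141), CXCL1 (-2.04 ± 0.55, 0.0209), CXCL2 (-2.95 ± 0.76, 0.0163), TNF (-2.21 ± 0.71, 0.0419) and FOS (-2.24 ± 0.64, 0.0258) also had lower effects in BEAS-2B, and each of these 5 calls ended without some single array. CXCL8 ended without replicate 2 of either control, and CXCL2 without BEAS-2B control replicate 2 or THP-1 3 h replicate 1. TNF ended without any 1 array other than the 2 BEAS-2B arrays of 3 h. FOS ended without any control array, BEAS-2B 3 h replicate 2 or THP-1 3 h replicate 1. CXCL1 ended without any of these but THP-1 control replicate 2. CCL2, CCL20, ICAM1, PTGS2, NFKBIA, TNFAIP3, ATF3, CYP1A1 and CYP1B1 did not pass. By list, 15 of 19 NF-kB feedback genes and 8 of 12 NRF2 targets had a lower effect in BEAS-2B and none a higher one (limma), while 7 of 15 G2/M genes had a higher one. Of 13 pattern recognition genes 8 had a higher one, but 4 of these (NOD2, TLR1, TLR2 and TLR6) were at background in BEAS-2B with and without dust and could not be seen to fall there. Of the 4114, 3465 had changed against control in THP-1 alone, 243 in BEAS-2B alone, 253 in both and 153 in neither.

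**Figure D2:**
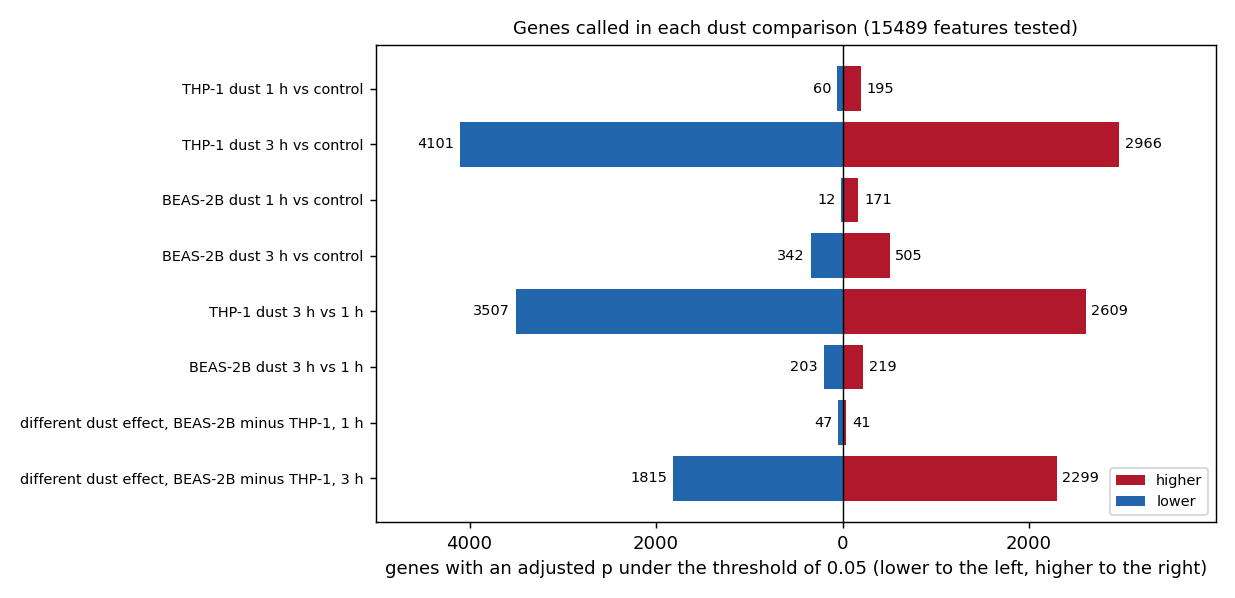
Number of genes or probes called in the 4 dust comparisons with control, the 2 comparisons of 3 h with 1 h and the 2 differences between the lines, higher to the right and lower to the left. THP-1 at 3 h had 2966 higher and 4101 lower against 505 and 342 in BEAS-2B at 3 h.

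The control arrays of the 2 lines were compared to describe their baselines and to check the line of each sample, because the source name of the THP-1 samples gives A459, unlike their titles and cell line field. All 15 measured epithelial markers were higher in BEAS-2B, among them KRT7, at least 83.7-fold, EPCAM, at least 58.0-fold, and CDH1, at least 48.1-fold. Of 17 monocyte markers 16 were higher in THP-1, among them TYROBP, at least 260-fold, CSF1R, at least 104-fold, and AIF1, 82.4-fold (-6.37 ± 0.14), and CD14 did not pass (-0.20 ± 0.17). Of 9 genes high in the A549 lung line, 8 of which other lists also hold, 7 were higher in BEAS-2B and none in THP-1 (limma). All 3 measured fibroblast markers were higher in BEAS-2B, and of 3 lymphocyte markers CD79B and NKG7 in THP-1, while CD79A was not well above background in either. The largest differences were in CAVIN1, at least 259-fold higher in BEAS-2B, FGFBP1, COL8A1, DKK3 and THBS1, at least 77.6-fold higher, and in ELANE, neutrophil elastase, at least 434-fold higher in THP-1, CTSG, AZU1, RNASE2 and TYROBP. In all 4983 genes or probes were higher in BEAS-2B and 4666 in THP-1. Of the genes followed in every comparison, IL6 (at least 3.52-fold), CYP1A1 (at least 3.39-fold), DUSP1 (at least 18.8-fold), CXCL1 (at least 3.82-fold), EGR1 (6.43-fold), CYP1B1 (4.34-fold), IL1B (4.16-fold), ATF3 (2.73-fold), CXCL8 (2.63-fold), CCL2 and HMOX1 were higher in BEAS-2B. TNF (at least 4.97-fold), FOS (at least 4.17-fold), PTGS2 and TNFAIP3 were higher in THP-1. NFKBIA and ICAM1 did not pass, and CCL20 and CXCL2 were at background in both. The calls of CCL2 and TNFAIP3 ended without any 1 control array or array of 1 h (up to 0.143 and 0.189), that of HMOX1 without THP-1 control replicate 2 (0.109), and that of PTGS2 without BEAS-2B control replicate 1 or either THP-1 control (up to 0.115).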

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

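Of the tests in this part, the use of median scaling as a test of the THP-1 count and the tests of carried-over RNA and of other probes were chosen only after the result was seen. Cyclic loess was added after the data were seen, but before its own result. The results listed here drew attention because a test of the difference between the lines passed its threshold, with the effect in BEAS-2B minus that in THP-1 given on the log2 scale as fitted. Line and dose changed together, so such a difference belongs to either or both.

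At 1 h, 88 genes or probes had a different dust effect. Genes with a higher effect in BEAS-2B were IL6 (4.96), EDN1 (3.61), TRIB1 (3.49), DUSP6 (2.96) and G0S2 (2.94). Genes with a lower effect were EGR1 (-2.79), IL1B (-3.39), KCNJ2 (-4.23), CCL3L3 (-6.91), CCL3L1 (-7.50), CCL3 (-8.03) and CCL4L1 (-8.04). IL6, EDN1 and G0S2 were at background in THP-1, and CCL3, CCL3L3 and CCL4L1 in BEAS-2B. So were CCL4L1 in THP-1 control, G0S2 in BEAS-2B control, 1 of the 2 THP-1 control arrays for CCL3 and IL1B and 1 BEAS-2B array of each group for CCL3L1, so the sizes of these differences are not exact. The calls of IL6, EDN1, TRIB1, G0S2 and IL1B ended without single arrays, as given above.

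At 3 h, 4114 genes or probes had a different dust effect. Higher in BEAS-2B were the effects on CXCL5 (5.04), CX3CR1 (4.64), CCR2 (4.51), ARHGEF3 (4.45), MMP3 (4.34) and IL6 (4.17). CX3CR1 and CCR2 were at background in BEAS-2B with and without dust, so these values restate the fall in THP-1. Lower were the effects on CXCL8 (-1.75), CXCL1 (-2.04), EGR1 (-2.19), TNF (-2.21), FOS (-2.24), HMOX1 (-2.28), CXCL2 (-2.95), IL1B (-3.27), DUSP1 (-3.87), SLC16A10 (-6.35), CCL3 (-6.70), CCN2 (-7.67), IGFBP3 (-8.66) and CCL4L1 (-8.67). Also at background were the other groups given above and 1 of the 2 THP-1 control arrays for CCL3, IL1B and HMOX1. The sizes of all these differences are not exact. The differences of CXCL8, CXCL1, EGR1, DUSP1 and CCN2 came largely from the controls, which were higher in BEAS-2B. CXCL1, for example, stood at 5.3 and 5.5 in THP-1 control and at 7.5 and 7.7 in BEAS-2B control. At 3 h it stood at 12.6 and 11.9 in THP-1 and at 13.1 and 11.7 in BEAS-2B. The calls of CXCL8, CXCL1, TNF, FOS and CXCL2 ended without single arrays, as given above.

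In THP-1 at 3 h 7067 genes or probes changed. The 75th percentile of signal was lowest on its arrays, so normalization was weighed as a cause. Median scaling gave 7696 calls, 1650 higher and 6046 lower, but moved the median of all genes to -0.30 log2. A shift can add calls, so quantile normalization stays open. Cyclic loess gave 7017 calls, 6509 among the 7067, arguing against a trend of fold change with intensity as the whole cause. A lower RNA yield and a response of the cells themselves also stay open, and neither was tested.

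IGFBP3 and CCN2 were not well above background in THP-1 control and rose in THP-1 at 3 h. RNA of BEAS-2B cells carried into these arrays would bring other epithelial transcripts along. Over 638 genes well above background in BEAS-2B at 3 h and absent from THP-1 control, the median gain in THP-1 was 0.27% of the BEAS-2B level (0.0632% over 12 epithelial markers), against 875% for IGFBP3 and 213% for CCN2, which argues against it. A probe that reads another transcript is argued against by the other kept probes, which rose for both of the 2 genes (7.71 ± 0.23 for IGFBP3 and 5.96 ± 0.23 for CCN2). That dust extract may induce both genes in THP-1 remains a hypothesis, found and tested on these same data.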

How the results depend on the processing

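Cyclic loess was the only alternative chosen after the data were seen. Of 339 calls of named genes, 281 held under every alternative run for them that kept all arrays, 260 whenever 1 array was left out and 253 under all of these, and no named gene reversed. Detection on all 12 arrays gave no value for genes dim on any array, nor for lists left too small, and the fits by line none for comparisons between lines or genes dim in every group of a line. The authors' value table, no background correction, no filter, all kept probes, median scaling and cyclic loess left every count of genes changed within 1.5 times its value as reported.

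With each line normalized and fitted on its own, 163 genes changed in THP-1 and 113 in BEAS-2B at 1 h, and the genes shared by both times in BEAS-2B fell to 64. With detection required on all 12 arrays fewer genes were tested. The counts against control were then 139 and 4618 in THP-1 and 69 and 458 in BEAS-2B at 1 and 3 h. From 1 to 3 h they were 4055 and 176, for the difference between the lines 26 and 2451, and between controls 5812. Shared genes fell to 124 between the times in THP-1, 38 in BEAS-2B and 28 between the lines at 1 h, and lists shifted in THP-1 at 3 h to 7. With a fold threshold of 2, which can only lower a count, 3309 genes changed in THP-1 and 366 in BEAS-2B at 3 h, 2642 and 197 from 1 to 3 h and 5631 between controls, and 164 were shared by the lines at 3 h. With an intensity trend and robust eBayes the genes shared at 1 h by the lines rose to 82; the cause was not tested.

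With an estimated correlation in camera, the lists shifted fell from 8 to 3 in THP-1 at 1 h, from 11 to 2 at 3 h and from 9 to 5 in BEAS-2B at 3 h, and from 9 to 7 in BEAS-2B at 1 h. The cause was not tested. Of the lists, 2 reversed in a setting. Heat shock in THP-1 at 1 h, called upward at a median of 0.24 log2, had a median of 0.0498 log2 and a downward direction in camera (adjusted p = 0.902) without THP-1 control replicate 1, and a median of 0.42 without control replicate 2. The pattern recognition list in THP-1 at 3 h, called downward at -1.25, had a median of 0.0282 (adjusted p = 0.87) with detection on all 12 arrays, which leaves out its dim receptors. The causes were not tested further. With fry, which tests a list against no change rather than against the other genes, 6 and 13 lists shifted in THP-1 at 1 and 3 h and 8 in BEAS-2B at each time. The calls of heat shock (adjusted p = 0.374) and adhesion genes (0.167) in THP-1 at 1 h, of aryl hydrocarbon receptor targets in BEAS-2B at 1 h (0.0929) and of immediate-early (0.146) and G2/M genes (0.324) in BEAS-2B at 3 h ended. Gained were aryl hydrocarbon receptor targets (0.00412) and metalloproteinases (0.00225) in THP-1 at 3 h and metalloproteinases in BEAS-2B at 3 h (0.00894). In BEAS-2B the pattern recognition call ended at 1 h with each line fitted on its own (0.085), no filter (0.0704) and detection on all 12 arrays (0.325), and at 3 h with no filter (0.125). That of aryl hydrocarbon receptor targets at 1 h ended with each line fitted on its own (0.0763).

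Leaving out 1 array at a time gave 149 to 318 genes changed in THP-1 at 1 h and 5889 to 7035 at 3 h, and 72 to 280 and 217 to 959 in BEAS-2B. From 1 to 3 h the range was 4650 to 6306 in THP-1 and 77 to 458 in BEAS-2B, and for the difference between the lines 30 to 143 at 1 h and 2767 to 4156 at 3 h. Between controls it was 8068 to 9858. Shared genes ranged from 140 to 276 between the times in THP-1, 31 to 190 in BEAS-2B, 30 to 90 between the lines at 1 h and 104 to 471 at 3 h. The highest BEAS-2B counts at 1 h came without an array of BEAS-2B at 3 h, which enters only through the pooled spread. Lists shifted ranged from 8 to 9 and 10 to 12 in THP-1 and from 8 to 10 at both times in BEAS-2B.

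The samples share only a replicate number, and nothing in the labels pairs them. With the replicate number as a block within each line, 321 and 7585 genes changed in THP-1 at 1 and 3 h and 181 and 992 in BEAS-2B, 85 and 4631 differed between the lines, and no count moved by more than 1.5 times. Single calls did change. The block ended those of IRAK2 in THP-1 at 1 h (adjusted p = 0.0638), HPRT1 in THP-1 at 3 h (0.0545), TGFA and TIPARP in BEAS-2B at 1 h (0.0509 and 0.0589), CXCL8 from 1 to 3 h in THP-1 (0.0555), and G0S2 and IL1B for the difference at 1 h (0.0904 and 0.0507). It brought 5 other named calls below the threshold: CXCL1 from 1 to 3 h in THP-1 (0.0499), NFKBIA from 1 to 3 h in BEAS-2B (0.0447), and CYP1A1, ICAM1 and NFKBIA for the difference at 3 h (0.0219, 0.0428 and 0.0491). Of the lists, 4 were gained: G2/M (0.0208) and cholesterol synthesis (0.0418) in THP-1 at 1 h, and metalloproteinases at 3 h in THP-1 (0.0492) and BEAS-2B (0.0414). Correlations of replicate deviations between groups were 0.341, 0.286 and 0.238 in THP-1 and 0.203, 0.00678 and -0.104 in BEAS-2B, taken across genes, which are not independent. Signal over background limits the dim genes: their folds are bounds.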

Other observations

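The tests of the difference between the 2 BEAS-2B arrays of 3 h were chosen only after the result was seen. Between the controls of the lines, of 19 interferon-stimulated genes 12 were higher in BEAS-2B and 3 in THP-1; IFIT1 was at least 9.39-fold and ISG15 3.33-fold higher in BEAS-2B. Of 12 heat shock genes 9 were higher in BEAS-2B, HSPA1A by 4.88-fold, as were 6 of 7 aryl hydrocarbon receptor targets and 10 of 15 G2/M genes. Of 13 pattern recognition genes 6 were higher in THP-1, NLRP3 at least 34.8-fold and IRAK3 16.4-fold, and 1 in BEAS-2B. Of 11 cholesterol synthesis genes 5 were higher in THP-1, SQLE by 2.15-fold, and 1 in BEAS-2B. Median scaling moved the median of all genes in this comparison from 0.01 to 0.11 log2.

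The 2 BEAS-2B arrays of 3 h of dust differed in the size of the response: over the 505 genes higher at 3 h, 358 were lower in replicate 2, with a median log2 rise of 0.98 against 1.22. RNA of control cells mixed into replicate 2 would leave the same share of the linear rise in every gene. Over 142 genes raised at least 4-fold in replicate 1, the 90th percentile of that share was 7.85 times the 10th (0.765 and 0.0975), against 2.75 times for the THP-1 arrays of 3 h, which argues against it. A harvest of replicate 2 between 1 and 3 h would leave immediate-early genes higher there; all 16 raised at 1 h were lower, by a median of -0.74 log2 (SE 0.10), which argues against it. A weaker exposure or a later harvest of replicate 2 may account for the median fraction of 0.786 of the rise seen there, but these cannot be told apart, since no label records the exposure or harvest of single cultures. Over 223 genes raised at 3 h in both lines and higher at 3 h than at 1 h in THP-1, replicate 2 was lower by a median of -0.30 log2 (SE 0.05), 172 of them lower. No array after 3 h shows whether such genes keep rising in BEAS-2B, so a later harvest stays open.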
